A study of Mus musculus with 46 samples.

How the data were processed

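Messenger RNA of the dorsal raphe nucleus was measured in 46 female F1 hybrid mice of C57 and CAST parents, in reciprocal crosses named F1i and F1r. The groups were P5 (7 and 7 animals), P15 (7 and 7) and adult (9 and 9). Per the labels, RNA was prepared with a column kit, libraries were made with the TruSeq kit, and 50 bp single-end reads were sequenced. The submitters name Novoalign and the mm9 build. The deposited values are whole-number counts per gene and allele, which the authors summed per gene in 3 tables with the same 15499 Ensembl identifiers. How reads were assigned to an allele, how reads matching several places were handled and which strand was counted is not stated. All 92 columns, a C57 and a CAST column for each of 46 animals, were matched to a sample by the names in the labels.

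Symbols and chromosomes were taken from a GENCODE annotation of a later build by Ensembl identifier, without using coordinates. It names 14969 of the 15499 genes and places 530 of them on the X chromosome, and 0 genes belong to the Y chromosome or the mitochondrial genome. The GC content of the transcripts was known for 96.58% of genes. No count was left out, and 91 genes with no count in any library were not tested.

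The comparisons, tests, gene lists and most alternatives were fixed before the data were examined. The allele models used the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with 1 column for each animal and allele, a term for each animal, and the total of both alleles of the animal as library size with no further scaling. The strain effect is the log2 CAST over C57 ratio averaged over the crosses. The parental effect is the F1i minus F1r difference of that ratio divided by 2. Genes with a mean summed count of 20 or more were tested. Each age was fitted alone, and changes with age were contrasts of a model of all 46 animals. Cross and age effects used the sum of both alleles, TMM scaling and the filterByExpr filter, with 6 groups sharing 1 spread for age. The 2 crosses weighed equally in age contrasts. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p of 0.05.

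For allele ratio overdispersion and allele coexpression each library was thinned at random to 3692778 counts, the smallest total. Overdispersion is the Pearson statistic of a binomial model with a mean for each cross divided by its degrees of freedom, tested one-sided against chi-square. Coexpression is the correlation over animals of the log2 CPM of both alleles with a prior count of 1 and the cross means removed. The X-linked share is the CAST percent of the summed counts of the X-linked list without Xist and the other escape genes. It was compared by exact permutation between crosses and by random permutation between ages, two-sided. Each share of a single animal has a 95% Wilson interval. The relation of this share with Xist was tested by permutation as a family of 8.

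Genes are named by a fixed rule. For the strain effect these were the 10 largest mean folds for each direction among genes called at all 3 ages in one direction, with a mean summed count of 100 or more and the same direction in every animal. For the parental effect they were every member of the imprinted lists called at any age and the 10 other genes with the largest effect among those called at 2 or more ages in one direction. For the cross effect they were the 5 largest for each direction and age. For age they were the 8 largest for each direction with a mean CPM of 10 or more at either age, and up to 4 members of each list by smallest p. For changes of allele effects with age they were the 8 largest for each direction with a mean summed count of 100 or more, and for overdispersion the 10 highest for each age with a mean thinned count of 50 or more. Ties went to the smaller p, and members of lists were also named as examples. Identifiers without a symbol are mostly given as counts, and a few genes that the rule takes are not named.

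There were 32 lists: maternally expressed imprinted, paternally expressed imprinted, X-linked, X inactivation escape, Y-linked, mitochondrially encoded, serotonergic, catecholamine, GABAergic and glutamatergic, neuropeptide, cell cycle, immature neuron and axon growth, myelin, oligodendrocyte precursor, astrocyte, microglia, endothelial and mural, ependymal and choroid plexus, blood, collagen and matrix, presynaptic, glutamate and GABA receptor, voltage-gated channel, immediate early, oxidative phosphorylation, cholesterol synthesis, cytosolic ribosomal protein, major histocompatibility, cerebellar, forebrain, cranial motor neuron, and DNA methylation and chromatin. The tables hold 0 of 4 Y-linked and 0 of 15 mitochondrially encoded names, 18 of 20 myelin names, 21 of 27 and 22 of 31 imprinted names and 101 of 110 X-linked names. The allele models were summarised for the imprinted, X-linked, escape, histocompatibility and ribosomal lists. For cross and age, lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists.

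The alternatives were DESeq2 1.42.0, limma on the log2 allele ratio, TMM factors for each allele column, DESeq2 size factors in edgeR, no count filter or a mean count of 100, the replicate number as a block, sums over the first number of the adult labels, fits of only the 2 ages compared, no thinning, no cross term, and leaving out the X-linked and imprinted lists. A GC correction over 20 bins of genes, this correction with the replicate block, and leaving out 1 adult F1i library that stood apart were chosen after the values were seen. Splits of the animals were drawn with fixed seeds, 100 for each age, cross, strain and parental comparison. For changes of allele effects with age 40 splits of 3000 genes drawn at random were fitted. The numbers in the labels did not meet the limit for pairing, a correlation of deviations from the group means over 0.1 in every pair, so replicate numbers served only as an alternative. Adults that share the second label number did deviate together more than other adults, with a median correlation of 0.205 against -0.172. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

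Libraries held 5100560 to 10319139 counts over both alleles at P5, 3692778 to 8032987 at P15 and 4912934 to 13085952 in adults. The models were tested on simulated data of the same depth. Of genes with a true log2 difference of 1, 97% to 100% were called, and of those with 0.5, 68% (cross effect at P15) to 100%, with 0 called in the wrong direction. Unchanged genes made up 1.96% to 7.35% of the simulated calls. The simulated genes varied independently with 1 spread for each age, and had no GC trend or other structure of the samples. These percentages therefore need not hold for the real libraries. For overdispersion the simulated SD of the allele share was 10%. Of changed genes with a mean count of 50 or more, 94.7%, 89.4% and 97.5% were called at the 3 ages. No cause of GC trends, sequencing day or litter is given in the labels, and none was used here.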

Results

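RNA from the dorsal raphe nucleus of 46 female F1 hybrid mice was compared by parental allele, by cross and by age. The animals came from crosses of the C57 and CAST strains in both directions, named F1i and F1r. There were 7 animals of each cross at P5, 7 of each at P15 and 9 of each as adults. The labels do not say which strain was the mother of F1i, so results are given by cross. For each animal the tables hold a C57 count and a CAST count of 15499 genes, and 91 genes had no count in any animal. No gene of the Y chromosome or of the mitochondrial genome was among them. Shares and CPM (counts scaled to a common library total) are means ± SD over animals, and log2 values are estimates ± SE.

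The CAST allele carried nearly all counts of Rps12, which encodes a protein of the small ribosomal subunit. Its strain effect, the log2 ratio of CAST over C57 averaged over both crosses, was 11.92 ± 0.19 at P5, 10.62 ± 0.12 at P15 and 7.84 ± 0.06 in adults. These folds rest on few C57 reads, so their size is uncertain. Rps19, another ribosomal protein gene, went the other way, with log2 ratios of -4.68 ± 0.07, -5.21 ± 0.07 and -5.57 ± 0.05 at the same ages. The C57 allele also exceeded CAST for Pon2, a paraoxonase gene (-4.51 ± 0.10, -4.24 ± 0.08 and -4.45 ± 0.06). Fabp5, which encodes a fatty acid binding protein, had a CAST share of only 8.3 ± 1.24% in F1i and 8.5 ± 1.12% in F1r at P5. For Gapdh, the glycolytic enzyme gene, the log2 ratio was -2.12 ± 0.08 at P5 and -5.35 ± 0.04 at P15.

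The other genes with the largest C57 excess at all 3 ages were 4933431E20Rik, the proteasome subunit gene Psmd2, the lipopolysaccharide binding gene Lbp, 4833420G17Rik, Rps15a and the chromatin protein gene Hmgb1. In adults their log2 ratios were -3.95 ± 0.04, -2.59 ± 0.06, -4.12 ± 0.08, -3.11 ± 0.04, -3.04 ± 0.02 and -3.02 ± 0.07. Rps12 was 1 of the 10 genes with the largest CAST excess at all ages, and the others were AK157302, Gm10874, Cbx3-ps7, Gm5436, Gm11847, Gm6969, the X-linked Mdm4-ps, ENSMUSG00000069106 and ENSMUSG00000091282. Each of the others had a CAST share of 99.3% or more in both crosses at every age. The C57 count of these 9 was at or near 0, so no fold is given for them. The rule by which these 20 genes were chosen takes only genes with the same direction in all animals. Several are ribosomal genes or pseudogenes with close copies elsewhere in the genome. How reads that match more than 1 copy were counted is not stated, so these shares are uncertain.

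Across all genes the strain effect passed an adjusted p of 0.05 for 7052 of 12070 genes at P5, 3804 with CAST and 3248 with C57 higher. At P15 the call was made for 7010 of 11996 (3731 and 3279), and in adults for 8597 of 12675 (4554 and 4043). The test was edgeR's quasi-likelihood test with a term for each animal, adjusted by the Benjamini-Hochberg method. Most of these effects were small, with a median size among called genes of 0.27, 0.29 and 0.25 log2 units. An effect of 1 log2 unit or more was seen for 744, 734 and 898 of the called genes. Of the 11650 genes tested at every age, 4558 were called in one direction at all 3 (2498 CAST and 2060 C57), against 700.5 if the ages were independent. Only 206 were called at all 3 ages with mixed directions. The ages share both genomes and the way reads were assigned, so a mapping bias toward 1 allele would also recur at each age. This overlap therefore does not tell such a bias from a difference in expression. Scaling each allele column by its own TMM factor moved the CAST share of the calls from 53.2% to 43.2% at P15, so the balance of directions is not firm.

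Among major histocompatibility genes in adults 3 favoured CAST and 5 favoured C57 of 9 tested, with 2 and 2 of 7 at P5 and 3 and 4 of 8 at P15. Ribosomal protein genes divided likewise, 6 and 4 of 14 at P5, 6 and 4 of 14 at P15 and 5 and 5 of 15 in adults. Maternally expressed imprinted genes had 2 CAST and 7 C57 strain effects of 19 at P5, 2 and 7 of 18 at P15 and 1 and 8 of 17 in adults. For paternally expressed imprinted genes the counts were 0 and 4 of 19, 0 and 7 of 20 and 0 and 5 of 20. Adjusted over the list alone, only the maternal list differed, with 2 and 6 at P5 and 1 and 7 at P15. X-linked genes favoured CAST almost throughout, 93 of 95 at P5, 91 of 92 at P15 and 95 of 96 in adults, with medians of 1.23, 1.15 and 1.21. Their C57 exceptions at P5 were Xist, the RNA that silences the X it is expressed from, and Rbm3, a cold-induced RNA binding gene. Of 5 genes known to escape X inactivation, 4 favoured CAST and Xist favoured C57 at each age, with medians of 0.71, 0.61 and 0.47. For the X-linked and escape lists the counts adjusted over the list alone were the same.

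Parental effects were called for known imprinted genes and for many X-linked genes. Of 252 genes that edgeR called at 2 or more ages in one direction, 174 were on the X, 31 were in the imprinted lists and 47 were in neither. The X-linked genes of an animal share its balance between the 2 X chromosomes, so these 174 are not separate effects. The CAST share of the X-linked list was 8.01, 2.32 and 6.54 points higher in F1i at P5, P15 and in adults. Meg3, a maternally expressed long RNA, had a CAST share of 99.04 ± 0.47% in adult F1i and 0.1 ± 0.16% in adult F1r. Peg3, a paternally expressed zinc finger gene, was the mirror image, at 0.1 ± 0.03% in F1i and 99.4 ± 0.89% in F1r. The potassium channel gene Kcnk9 stood at 99.8 ± 0.32% and 0.3 ± 0.58%, and the calcitonin receptor gene Calcr at 99.2 ± 0.57% and 2.3 ± 1.202%. In the other direction stood the retrotransposon-derived gene Peg10 (0.2 ± 0.11% and 99.8 ± 0.24%) and the guanine nucleotide exchange factor gene Rasgrf1 (0.5 ± 0.13% and 99.02 ± 0.13%). Each held its direction in all 9 adults of both crosses.

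**Figure D1:**
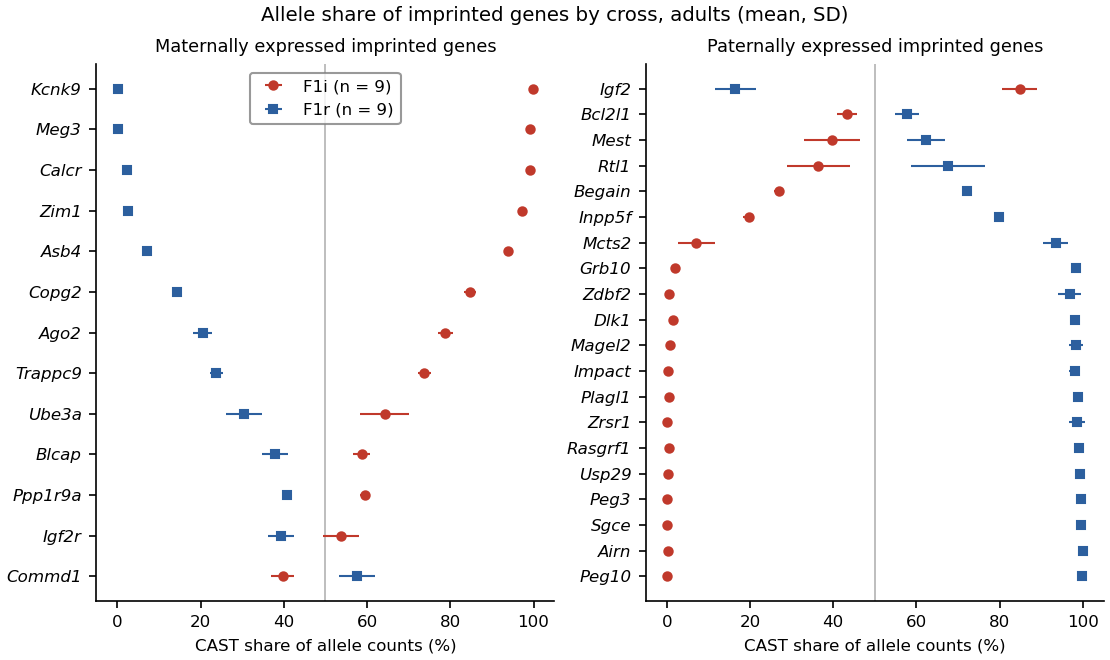
CAST share of counts of imprinted genes in adult F1i and F1r animals, mean ± SD over 9 animals of each cross. A share near 100% in F1i and 0% in F1r means that the allele followed the cross.

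Other maternally expressed genes with a higher CAST share in F1i had smaller contrasts. Asb4 had adult shares of 93.8 ± 0.96% and 7.1 ± 1.27%, Zim1 97.3 ± 0.80% and 2.5 ± 0.59%, and Copg2, a coat protein gene, 84.8 ± 1.34% and 14.3 ± 1.22%. For Ago2, which encodes a small RNA effector, the adult shares were 78.8 ± 1.82% and 20.5 ± 2.32%. Trappc9, a trafficking gene linked to microcephaly, stood at 73.7 ± 1.55% and 23.8 ± 1.53%. Ube3a, the ubiquitin ligase gene of Angelman syndrome, stood at 64.2 ± 5.93% and 30.4 ± 4.36%. Blcap, Igf2r and Ppp1r9a were nearer to balance, with parental effects in adults of 0.62 ± 0.03, 0.43 ± 0.05 and 0.55 ± 0.01 log2 units. The parental effect is the F1i minus F1r difference of the log2 CAST over C57 ratio divided by 2. H19, a growth-restricting RNA, and the cell cycle inhibitor gene Cdkn1c were expressed mainly at P5, with shares of 99.6 ± 0.34% and 11.96 ± 8.07% for H19 and 97.6 ± 1.70% and 4.6 ± 4.75% for Cdkn1c. Osbpl5 passed only at P5 (0.13 ± 0.03, adjusted p = 0.01), and not with DESeq2. Commd1 alone of the maternal list was reversed, with a parental effect of -0.95 ± 0.10 at P5, -0.29 ± 0.07 at P15 and -0.49 ± 0.05 in adults, where its shares were 39.8 ± 2.75% and 57.6 ± 4.39%. The P15 call of Commd1 was lost with DESeq2, with limma and with the replicate block.

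Among paternally expressed genes, Sgce, Usp29, Plagl1, Zdbf2, Zrsr1, Airn, Impact and Dlk1 had an adult CAST share of 1.6% or less in F1i and 96.8% or more in F1r. Magel2, of the Prader-Willi region, stood at 0.1 ± 0.27% and 99.6 ± 0.37% at P5. The growth factor receptor adaptor gene Grb10 had 2.0 ± 0.59% and 98.2 ± 0.46% in adults, and Mcts2 7.1 ± 4.42% and 93.4 ± 2.94%. The phosphatase gene Inpp5f had adult shares of 19.7 ± 1.35% and 79.8 ± 0.77%. Begain, a postsynaptic gene, stood at 26.9 ± 1.23% and 72.2 ± 0.91%, and Mest, a hydrolase-like gene, at 39.7 ± 6.67% and 62.3 ± 4.59%. The survival gene Bcl2l1 had the smallest adult contrast of the list, -0.42 ± 0.03. Igf2, the fetal growth factor gene, ran against its list, with adult shares of 84.8 ± 4.21% and 16.5 ± 4.91%. Rtl1 changed side between ages, at 0.73 adjusted p and -0.21 ± 0.12 at P5, 1.59 ± 0.14 at P15 and -0.95 ± 0.11 in adults. Rtl1 and the RNA gene Mir1188 lie in 1 imprinted region with antisense transcripts, and the strand of counting is not stated, so the side of Rtl1 is uncertain.

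Outside the lists the largest parental effects called at 2 or more ages were on Gm38393 and A230006K03Rik, which had shares of 1.3% or less in F1i and 98.4% or more in F1r, and on Nespas and Mir1188, with the reverse. ENSMUSG00000078690 and 3 further identifiers without a symbol were as strong. Gm11410 and Gm13339 had nearly all counts on CAST in F1i and nearly no counts in F1r. Named after the values were seen, Gnas, the stimulatory G protein gene, had P5 shares of 5.5 ± 2.09% and 95.1 ± 1.82%. Herc3, an E3 ligase gene, had adult shares of 74.5 ± 2.44% and 26.0 ± 1.56%. The peptidase gene H13 and the tRNA synthetase gene Wars had smaller P5 effects of 1.49 ± 0.03 and -0.43.

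Over all genes a parental effect was called for 327 of 12070 at P5 (283 with a higher CAST ratio in F1i, 44 lower), 89 of 11996 at P15 (55 and 34) and 344 of 12675 in adults (287 and 57). Outside the X chromosome the counts were 100, 74 and 113. DESeq2 called 120 at P5 and 138 in adults, and limma on the log2 allele ratio called 177 in adults, so the length of these lists depends on the tool. The loss fell mainly on the X, where edgeR called 227 at P5 and 231 in adults, DESeq2 53 and 48, and limma 192 and 78. Outside the X DESeq2 called 67 at P5 and 90 in adults. Maternally expressed genes had 15 higher and 1 lower of 19 at P5, 13 and 1 of 18 at P15 and 12 and 1 of 17 in adults, with medians of 2.07, 1.12 and 1.03. Adjusted over the list alone these were 15 and 2, 14 and 2, and 13 and 1. Paternally expressed genes had 1 higher and 17 lower of 19, 2 and 18 of 20, and 1 and 19 of 20, with medians of -5.80, -5.58 and -6.17, and the same counts adjusted over the list alone. X-linked genes had 69 higher and 1 lower of 95 at P5, 4 and 0 of 92 at P15 and 64 and 1 of 96 in adults. Adjusted over the list alone they had 84 and 1, 12 and 0, and 87 and 2. Major histocompatibility and ribosomal protein genes had 0 parental effects at every age, also adjusted over the list alone, and genes escaping X inactivation had 1 and 1, 0 and 0, and 0 and 1 of 5.

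Total counts differed between crosses most for 4 pseudogene loci at P5. Parts of their reference transcripts also occur in mitochondrial transcripts, so these counts may not come from the loci themselves. Gm13340 had 5864 ± 372 CPM in F1i and 2.31 ± 2.73 in F1r, Gm13341 1854 ± 99 and 0.244 ± 0.646, Gm11410 731 ± 57.1 and 0.308 ± 0.33, and Gm13339 558 ± 67 and 0.452 ± 0.354. H19 was 3-fold higher in F1i (1.61 ± 0.10 log2 units, adjusted p = 1.1e-17). Genes of myelin were lower in F1i. Mobp, which encodes a myelin-associated basic protein, had 138 ± 10.6 and 231 ± 32.3 CPM (-0.75 ± 0.05, adjusted p = 4.8e-15). Ermn, a cytoskeletal gene of oligodendrocytes, Mal, a proteolipid gene of myelin, and Tmem125 followed with -0.72 ± 0.12, -0.56 ± 0.10 and -0.64 ± 0.14. The leukocyte gene Cd53 completed the 5 largest (-0.57 ± 0.15, adjusted p = 0.048), but lost its call with DESeq2 (adjusted p = 0.12), without a count filter, with the replicate block (0.0714) and with the GC correction (0.0557). The call of Gm13340 was lost with DESeq2, whose adjusted p was 0.339.

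Of 15 myelin genes tested at P5, 11 were lower in F1i than in F1r and 0 were higher (0 and 12 adjusted over the list alone). The median was -0.46, and camera with its preset correlation gave an adjusted p of 6.7e-20 (adjusted p = 0.08 with an estimated correlation). Mag (-0.49 ± 0.05) and Mbp (-0.46 ± 0.04), which encode adhesion and structural proteins of myelin, were among the 11. Each animal of F1i had a lower mean log2 CPM over the 14 myelin genes outside the X chromosome than any F1r animal, 5.79 ± 0.096 against 6.19 ± 0.129 (exact permutation p = 0.000583).

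**Figure D2:**
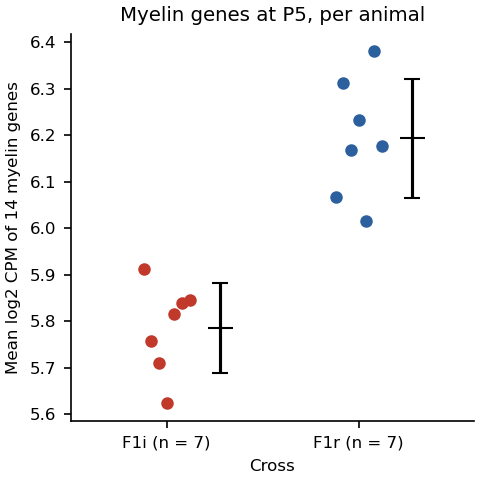
Mean log2 CPM of 14 myelin genes in each P5 animal, with the mean ± SD of each cross.

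Of 15 serotonergic genes tested at P5, 0 were higher and 3 were lower in F1i (0 and 6 adjusted over the list alone). These were Tph2, the rate-limiting enzyme gene of serotonin synthesis (-0.28 ± 0.06), the serotonin transporter gene Slc6a4 (-0.20 ± 0.05) and the transcription factor gene Fev (-0.31 ± 0.07). Camera gave an adjusted p of 0.04 for this list (adjusted p = 0.84 with an estimated correlation), and DESeq2 called none of these 3 genes. Cranial motor neuron genes had 0 up and 1 down of 5 (0 and 3 adjusted over the list alone, median -0.30), and GABAergic and glutamatergic genes 0 and 1 of 6 (0 and 3 adjusted over the list alone, median -0.09), both without a camera call (adjusted p = 0.145 and 0.254). Dcx, Sox4, Dpysl3, Dpysl5 and Crmp1, genes of migrating neurons and growing axons, were higher in F1i, 5 of 21 (6 adjusted over the list alone), and Dcx led with 0.25 ± 0.03. Of these Sox4 was not called with DESeq2 and Crmp1 not with the replicate block or the GC correction. Paternally expressed imprinted genes had 2 up and 3 down of 21 (2 and 9 adjusted over the list alone), with camera at 0.04 (adjusted p = 0.48 with an estimated correlation). Their sums fell for Rasgrf1 (-0.31 ± 0.04), Impact (-0.26 ± 0.03) and Inpp5f (-0.13 ± 0.03). Maternally expressed genes had 2 up and 3 down of 19 (2 and 4 adjusted over the list alone), with Ube3a at -0.45 ± 0.07. Presynaptic genes had 0 up and 3 down of 17, namely Vamp1, Syt2 and Cplx1.

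At P15 and in adults few genes differed between crosses. Gm13341, Gm13340, Gm11410 and Gm13339 again had the largest effects, and Gm13340 had 17780 ± 1396 and 32.2 ± 13.2 CPM at P15 and 12830 ± 1955 and 1.72 ± 0.952 in adults. H19 stayed higher in F1i at P15 (2.01 ± 0.21, adjusted p = 7e-05). Ube3a was lower in F1i at both ages, 25.5 ± 3.65 and 41.2 ± 3.69 CPM at P15 (-0.69 ± 0.09, adjusted p = 0.0019) and 23.9 ± 1.56 and 35.4 ± 3.25 in adults (-0.57 ± 0.06, adjusted p = 4.7e-06). Xlr3c, of the X-linked Xlr family, had 2.40 ± 0.97 CPM in adult F1i and 0.179 ± 0.131 in F1r. Cplx1, a complexin gene of vesicle release, was lower in adult F1i (-0.28 ± 0.06, adjusted p = 0.038). Xlr3c belongs to a family of near-identical copies, so its counts are uncertain.

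A cross effect was called for 151 of 12919 genes at P5 (64 higher in F1i, 87 lower), 6 of 12850 at P15 (5 and 1) and 15 of 13516 in adults (13 and 2). In adults 1244 genes had an unadjusted p below 0.05. The adult count rose to 54 with DESeq2, 77 with the replicate block (the second label number), 52 with the GC correction, 174 with both and 306 when counts were summed over the first label number, and each kept the 15 genes. At P15 DESeq2 called 10. In adults myelin genes had 0 up and 0 down of 18 (0 and 2 adjusted over the list alone), a median of -0.17 and a camera adjusted p of 4.7e-05 (adjusted p = 0.47 with an estimated correlation). Cholesterol synthesis genes had 0 of 17 (1 lower adjusted over the list alone) and a camera adjusted p of 0.041 (adjusted p = 0.47 with an estimated correlation). At P15 microglia genes had 0 of 12, a median of -0.12 and a camera adjusted p of 0.0046 (adjusted p = 0.64 with an estimated correlation).

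Between P5 and P15 myelin genes rose most. Mal went from 14.3 ± 3.68 to 476 ± 98.5 CPM (5.08 ± 0.11), Ermn from 10.2 ± 3.31 to 252 ± 52.3 (4.66 ± 0.11) and Mobp from 185 ± 54 to 2860 ± 483. Opalin, a gene of myelinating oligodendrocytes, and Etnppl, a phospho-lyase gene of astrocytes, were at 0.17 ± 0.179 and 0.559 ± 0.311 CPM at P5 and at 89.3 ± 15.1 and 88.9 ± 11.9 at P15. All 18 myelin genes rose (median 3.33, camera adjusted p = 1.0e-32). Over the same 10 days Dpysl3, a collapsin response mediator gene of growing axons, fell from 3686 ± 208 to 422 ± 22.1 CPM (-3.12 ± 0.04).

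Other large rises were of the cadherin gene Cdh19 (5.20), BC030499 (4.80) and Cyp2j12 (4.55). Other large falls were of Islr2 (-4.41 ± 0.14), Trim67 (-3.30), Dpysl5 (-3.11), the myelin inhibitor receptor gene Rtn4r (from 16.6 ± 2.18 to 2.06 ± 0.788 CPM), the adhesion receptor gene Cxadr (-2.98) and St8sia2, which adds polysialic acid to NCAM (-2.85). Immature neuron genes had 0 up and 19 down of 21 (median -1.41, camera adjusted p = 1.7e-18), with Crmp1 at -2.70 and Tubb2b at -2.35. Among astrocyte genes 12 rose and 2 fell of 15 (median 0.96, camera adjusted p = 3.1e-09), led by the connexin gene Gjb6 (4.25 ± 0.06) and Aldoc (1.70). Microglia genes had 11 up and 1 down of 12 (median 0.86, camera adjusted p = 2.3e-04, adjusted p = 0.11 with an estimated correlation), with Tmem119 at 1.90 and Ctss at 1.69. Oxidative phosphorylation genes had 18 up and 0 down of 20 (median 0.82, camera adjusted p = 1.4e-06, adjusted p = 0.07 with an estimated correlation), with the succinate dehydrogenase gene Sdha at 1.26. DNA methylation and chromatin genes had 1 up and 9 down of 16 (median -0.47, camera adjusted p = 0.022, adjusted p = 0.086 with an estimated correlation). In this list the methyltransferase genes Dnmt3a and Dnmt1 fell by 1.48 and 1.28 log2 units.

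**Figure D3:**
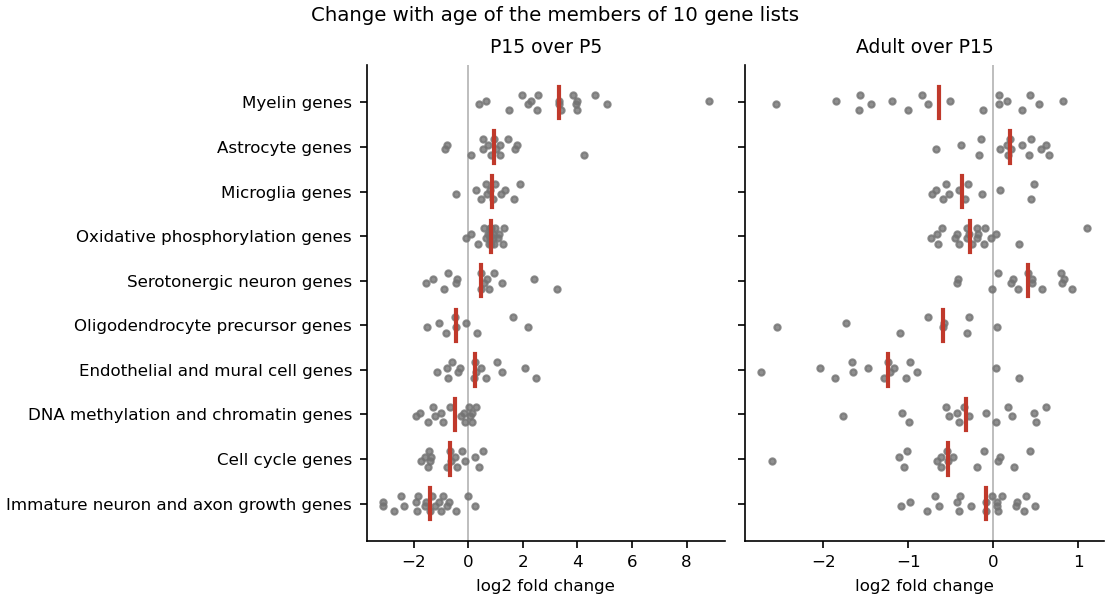
Log2 fold changes of the members of 10 gene lists between P5 and P15 and between P15 and adults, with the median of each list in red.

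Tph2 and Ddc, genes of serotonin synthesis, and Maob, a monoamine oxidase gene that breaks monoamines down, rose between P5 and P15. Tph2 went from 104 ± 16.7 to 546 ± 88.3 CPM (2.40 ± 0.08) and stayed at 540 ± 63.9 in adults. Maob rose from 6.11 ± 1.66 to 59.2 ± 9.85 (3.27 ± 0.11), and Ddc from 107 ± 13.3 to 255 ± 38.4 (1.25 ± 0.06). The serotonergic list had 9 up and 5 down of 15 (median 0.48, camera adjusted p = 0.15). Channel and receptor genes moved in both directions, with the potassium channel gene Kcna1 (2.34) up and the receptor genes Grin2d (-2.32), Gabra5 (-1.30) and Grin3a (-1.26) down. Voltage-gated channels had 7 up and 12 down of 20 (10 and 9 under the GC correction), and glutamate and GABA receptors 9 up and 10 down of 22. Of the imprinted genes, Impact and Rasgrf1 rose (2.05 and 1.85). Paternally expressed genes had 11 up and 9 down of 21, and maternally expressed genes 7 up and 10 down of 19.

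The remaining lists showed no camera call between P5 and P15. Cell cycle genes had 3 up and 12 down of 16 (median -0.65, with Mcm5 at -1.75), collagen and matrix genes 4 and 10 of 16, forebrain genes 0 and 5 of 5 (Bcl11b -2.07) and cholesterol synthesis genes 6 and 9 of 17. Endothelial and mural genes had 9 and 5 of 15, neuropeptide genes 9 and 3 of 15 (Vip 2.51), major histocompatibility genes 7 and 1 of 9 (B2m 1.15), immediate early genes 6 and 2 of 10 (Fos 1.95) and ribosomal protein genes 9 and 4 of 16. Presynaptic genes had 6 and 8 of 19, with Vamp1 at 1.61 and Stx1a at -1.53. Oligodendrocyte precursor genes had 3 and 5 of 9, with a median of -0.44 that was 0.31 under the GC correction, and Neu4 at 2.21. Small lists had 2 up and 0 down of 3 (blood, Hbb-bs 1.92), 2 and 1 of 6 (catecholamine neurons, Th 0.51), 1 and 2 of 3 (cerebellum), 2 and 2 of 5 (cranial motor neurons, 4 and 1 under the GC correction), 5 and 2 of 11 (ependyma and choroid plexus), 2 and 2 of 7 (GABAergic and glutamatergic neurons, 3 and 4 under the GC correction) and 2 and 3 of 5 (escape from X inactivation). X-linked genes had 44 and 38 of 98, but 33 and 48 under the GC correction. Adjusted over the list alone, cholesterol genes had 7 and 9, histocompatibility genes 7 and 2 and oxidative phosphorylation genes 19 and 0, with no other difference. The median, the mean and the camera direction differed in sign for the precursor, voltage-gated channel, presynaptic and GABAergic and glutamatergic lists.

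Oligodendrocyte precursor genes fell from P15 to adulthood. Enpp6, a phosphodiesterase gene of newly formed oligodendrocytes, fell from 92.2 ± 13 to 9.11 ± 1.46 CPM (-3.34 ± 0.07) and Gpr17, a receptor gene of committed precursors, from 661 ± 87.4 to 113 ± 14.7 (-2.55 ± 0.06). Precursor genes had 0 up and 8 down of 9 (median -0.59, camera adjusted p = 9.3e-10), with Pdgfra at -1.09 and Neu4 at -1.73. Myelin genes had 5 up and 10 down of 18 (median -0.64, camera adjusted p = 1.2e-04, adjusted p = 0.36 with an estimated correlation). The vascular growth factor receptor gene Kdr fell from 27.5 ± 9.13 to 4.17 ± 1.03 CPM (-2.73 ± 0.13), and endothelial and mural genes had 1 up and 13 down of 15 (median -1.24, camera adjusted p = 4.5e-12). Cartpt, a neuropeptide precursor gene, rose from 46.1 ± 33 to 456 ± 175 CPM (3.28 ± 0.27).

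Other large rises into adulthood were of the matrix phosphoprotein gene Dmp1 (2.91), BC035947 (2.28), the heat shock factor gene Hsf4 (2.26), Pcolce2 (2.22), Ppp1r1b, which encodes DARPP-32 (2.12), 1700003D09Rik (2.05) and Gm8566 (2.02). Other large falls were of the cyclophilin gene Ppic (-3.52 ± 0.10), Depp1 (-3.30), AU021092 (-2.89), Rab7b (-2.75) and the pseudogenes Gm13341 and Gm11410. Presynaptic genes had 13 up and 3 down of 19 (median 0.40, camera adjusted p = 0.017, adjusted p = 0.55 with an estimated correlation), with Cplx1 at 0.99. Voltage-gated channels had 11 up and 3 down of 20 (median 0.33, camera adjusted p = 0.017, adjusted p = 0.55 with an estimated correlation), with the sodium channel gene Scn4b at 1.72 and Hcn2 at 1.53. Collagen and matrix genes had 0 up and 14 down of 16 (median -0.54, camera adjusted p = 0.017, adjusted p = 0.36 with an estimated correlation), with the fibronectin gene Fn1 at -1.32. Blood genes had 0 up and 3 down of 3 (median -1.85, camera adjusted p = 0.0041, adjusted p = 0.16 with an estimated correlation), with Hbb-bt at -2.03. Serotonergic genes had 11 up and 2 down of 15 (median 0.42, camera adjusted p = 0.069), among them Fev (0.93) and the autoreceptor gene Htr1a (0.81). Under the GC correction these were 8 up and 2 down with a median of 0.23. For the lists named in this interval the counts adjusted over the list alone were the same.

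Across the whole interval from P5 to adulthood, Etnppl (8.53 ± 0.12), Opalin (7.98 ± 0.20), Cdh19 (5.54 ± 0.15), the secreted Wnt antagonist gene Sfrp5 (5.10 ± 0.16), Fam107a (5.01 ± 0.09), Ptgds (4.71 ± 0.35), Ermn (4.54 ± 0.11) and the transferrin gene Trf (4.53 ± 0.10) rose most. Falls were largest for H19 (-4.78 ± 0.12), Ppic (-4.02 ± 0.09), Cxadr (-3.99 ± 0.06), Kdr (-3.52 ± 0.12), Dpysl3 (-3.51 ± 0.03), Islr2 (-3.50 ± 0.10), the basement membrane gene Nid1 (-3.36 ± 0.06) and Tubb2b (-3.33 ± 0.05). All 21 immature neuron genes fell (median -1.23, camera adjusted p = 4.1e-20), all 18 myelin genes rose (2.08, camera adjusted p = 1.1e-18), and cell cycle genes had 1 up and 14 down of 16 (-1.05, camera adjusted p = 0.0019). DNA methylation and chromatin genes had 2 up and 12 down of 16 (-0.89, camera adjusted p = 0.00032), with Dnmt3a at -2.54 and Tet1 at -2.02. Astrocyte genes had 12 up and 3 down of 15 (0.90, camera adjusted p = 4.7e-10). Camera also called oxidative phosphorylation (20 up and 0 down of 20), serotonergic (9 and 4 of 15), endothelial and mural (3 and 11 of 15), precursor (2 and 7 of 9), microglia (9 and 2 of 12) and collagen and matrix genes (4 and 12 of 16). These 6 were not called with an estimated correlation, with an adjusted p of 0.26 for oxidative phosphorylation and 0.34 for the others. Adjusted over the list alone, 4 endothelial and mural genes rose and the other counts of this paragraph were the same.

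The age tests called 11377 of 13637 genes between P5 and P15 (5798 up, 5579 down), 10183 between P15 and adults (5046 and 5137) and 11201 between P5 and adults (5543 and 5658). Libraries differed in how counts followed gene GC content, and the GC correction turned 527, 57 and 106 of the jointly called genes to the opposite direction. Features of handling that the labels do not record may have gone with age, so age and preparation cannot be separated.

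The contrast in allele share between crosses changed with age for several imprinted genes. The strand of counting is not stated and cell types were not separated, so overlapping transcripts or the mix of cells may contribute. For Mest the F1i minus F1r difference in CAST share went from -88.4 points at P5 to -47.1 at P15 and -22.6 in adults (2.53 ± 0.15 log2 units between P5 and P15, adjusted p = 1.8e-21). Inpp5f went from -92.4 to -76.3 and -60.1 points (1.77 ± 0.05 and 0.86 ± 0.04 for the 2 steps). Blcap fell from 58.8 to 27.6 and 20.9 points (-1.12 ± 0.07 between P5 and P15). Ube3a was weakest at P15, with 43.7, 12.2 and 33.8 points (-1.02 ± 0.11, then 0.69 ± 0.09, adjusted p = 8.9e-10 and 8.4e-08). Herc3 gained steadily, 30.2, 36.5 and 48.6 points (0.64 ± 0.04 from P5 to adults), and Begain was strongest at P15, with -28.7, -54.7 and -45.3 points.

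**Figure D4:**
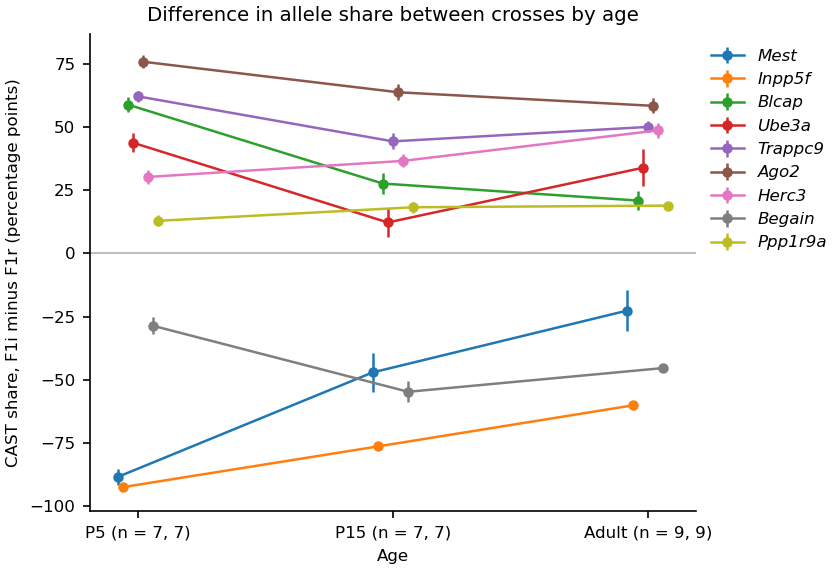
F1i minus F1r difference in CAST share, in percentage points, at P5, P15 and in adults for 9 genes. Bars are the root of the summed squares of both crosses' SDs.

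Grb10 became more exclusive (-84.9, -94.0 and -96.2 points), as did Dlk1 (-91.8, -95.2 and -96.6), Zim1 (87.3, 93.3 and 94.8), Calcr (92.4, 94.1 and 97.0) and Copg2 (61.7, 68.6 and 70.4). Trappc9 (62.0, 44.2 and 49.9), Ago2 (75.7, 63.6 and 58.3) and H13 (47.2, 35.4 and 32.6), which lie in the same regions as other imprinted genes, lost contrast after P5. Ppp1r9a rose from 12.8 to 18.2 points between P5 and P15, Commd1 moved from -30.9 to -9.4 and Crls1, a cardiolipin synthase gene, from -7.8 to 2.8. Klhdc10 fell from 21.4 points at P15 to 12.7 in adults, and the X-linked Mid1 and Gm15726 from 11.8 and 12.9 to -6.2 and -11.1. Impact and Rasgrf1 were near complete at every age, and their changes (-1.99 ± 0.34 and 1.16 ± 0.29) came from a few reads of the weaker allele. The changes of Gm11410, Gm13339 and Gm13340 also rest on near 0 counts in F1r. In all, parental effects differed for 19 of 12430 genes between P5 and P15, 16 between P15 and adults and 30 between P5 and adults. Limma on the log2 allele ratio called 36 and 26 for the first 2 steps.

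Strain effects moved with age for many more genes. Spp1, the osteopontin gene, had a CAST share of 32.9 ± 3.1% at P5 and 55.2 ± 4.4% at P15 (1.32 ± 0.06, adjusted p = 2.8e-28). Gapdh fell from 18.9 ± 3.9% to 2.5 ± 0.55% (-3.24 ± 0.15), Itih3, a hyaluronan-binding inhibitor gene, from 69.4 ± 4.0% to 41.1 ± 1.9% (-1.70 ± 0.05) and the securin gene Pttg1 from 28.2 ± 1.6% to 11.4 ± 2.6% (-1.59 ± 0.08). Between P15 and adults the oligodendrocyte repressor gene Zfp488 rose from 60.1 ± 2.9% to 76.8 ± 3.0% (1.12 ± 0.07). Pfdn5, a prefoldin gene, fell from 98.3 ± 0.91% to 82.0 ± 2.0% (-3.61 ± 0.15) and the oligosaccharyltransferase gene Tusc3 from 95.6 ± 1.8% to 80.7 ± 2.8% (-2.44 ± 0.14). Tmem119, a microglia gene, rose from 20.96 ± 7.8% at P5 to 44.4 ± 2.9% in adults (adjusted p = 2e-14).

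Between P5 and P15 the CAST share also rose for the complement gene C3, Sec14l3, Tusc3, Rbm3, Rpl28, Hebp2 and Gm11410 and fell for Smyd1, Rpl9, Ass1, Mrps33 and Ankub1. From P15 to adults it rose for Rpl9, Rpl13, Sec14l3, Kcnmb1, Gm6969, Col6a5 and Gpr153 and fell for ENSMUSG00000048149, Gm14038, Gm10704, Rps12, Gm11410 and Gm13339. Over the whole interval it rose for Sec14l3, Col6a5 (48.6 ± 6.0% to 82.4 ± 2.6%), Rbm3, Zfp488, Fbln7, Nat8f1 and ENSMUSG00000069106 and fell for Rps12, Gm14038, Pfdn5, ENSMUSG00000048149, Gm10704, Gapdh, Pttg1 and Ass1. Folds of the genes with a share near 100% rest on few C57 reads. Age changed the strain effect of 2325 genes between P5 and P15 (1126 toward CAST, 1199 toward C57), 1923 between P15 and adults (928 and 995) and 3675 over the whole interval (1747 and 1928), of 12430. With TMM factors per allele column the share moving toward CAST went from 48.4% to 34.6% for the first step and from 48.3% to 63.3% for the second.

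The allele ratio of X-linked genes varied between animals beyond counting error. Gprasp1, a receptor sorting gene on the X, had CAST shares of 55.5% to 76.3% over P5 animals, with a dispersion ratio of 45.3 where 1 means counting error alone. Xist ranged from 24.1% to 43.7% at P5 (42.6). Off the X, Psap, the saposin gene, ranged from 49.9% to 60.2% at P15 (26.1), Abat, a GABA transaminase gene, from 39.8% to 47.3% (16.7) and Reep5 from 52.1% to 58.7% (16.2). The other highest ratios were of Ids, Dgkk, Maged2, L1cam, Usp11 and Gnl3l at P5, Impact, Peg3 and Meg3 at P15 and Gpm6b, Eif1ax and Maged1 in adults. In Impact, Peg3 and Meg3 the variation is in a few percent of reads of the weaker allele.

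After thinning every library to 3692778 counts, 124 of 10679 genes were overdispersed at P5 (103 of them X-linked), 176 at P15 (90) and 221 in adults (168), by a one-sided chi-square test with Benjamini-Hochberg adjustment. At all 3 ages 63 were called, against 0.042 if the ages were independent, and 6 of the 63 were not X-linked. Without thinning 196, 279 and 507 were called, and without the cross term 263, 251 and 343. Leaving out the X-linked and imprinted lists left 75, 123 and 148. The median ratio over genes was 0.983, 1.025 and 1.026. Outside the X it was 0.968, 1.015 and 1.012, against 0.946, 0.946 and 0.960 when the reads of each gene were split at random between the alleles.

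The CAST and C57 alleles of a gene rose and fell together between animals at P15 and in adults. The median correlation over genes was 0.0923 at P5, 0.490 at P15 and 0.412 in adults, positive for 61.1%, 88.6% and 86.6% of genes. Genes on the X chromosome behaved otherwise, with medians of -0.282, 0.267 and 0.017. Outside the X the medians were 0.103, 0.498 and 0.423. Random splits of each animal's reads between the alleles gave 0.117, 0.524 and 0.439 there, so the medians largely follow how far total levels differ between animals. The P15 minus P5 difference of 0.398 exceeded all other values among 100 regroupings of the animals (highest 0.0987), as did that of 0.320 between adults and P5 (0.0705), while -0.0781 between adults and P15 was reached by 4 of 100. Without thinning the adult median of 0.579 lay above the P15 median of 0.532, so the direction between P15 and adults is not firm. Without 1 adult F1i library that stood apart the adult median was 0.355. The genes share animals and are not independent replicates.

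The CAST X carried more expression than the C57 X in all 46 animals. The CAST share of 96 X-linked genes ran from 57.4% to 78.4%, and that of Xist, which marks the inactive X, from 21.4% to 43.9%. The sum of both shares was 100.9 ± 1.12%. At P5 F1i animals had an X-linked share of 73.5 ± 2.83% and F1r of 65.5 ± 5.11% (exact permutation p = 0.00175, adjusted p = 0.0105). At P15 the shares were 69.9 ± 3.86% and 67.6 ± 3.71% (exact permutation p = 0.283, adjusted p = 0.566), and in adults 71.4 ± 4.75% and 64.8 ± 4.79% (exact permutation p = 0.0119, adjusted p = 0.0357). Genes outside the X stood at 49.9% to 51.5% in each animal. No age difference passed (-0.734, -0.69 and -1.42 points, each with an adjusted permutation p of 0.702). Their sign turned with all genes on the X (0.422, 0.243 and 0.665 points), so no direction is given.

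**Figure D5:**
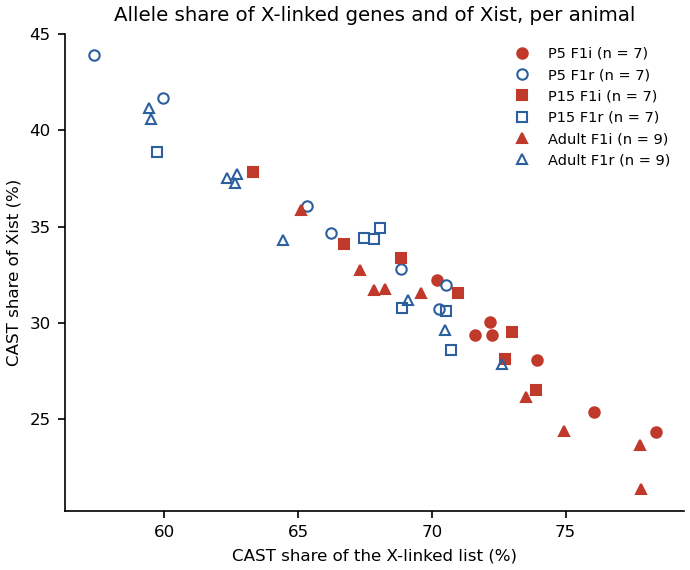
CAST share of Xist against the CAST share of 96 X-linked genes in each of 46 animals, by age and cross.

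Across animals the shares of Xist and of the X-linked genes ran opposite. With the group means removed r was -0.978 and rho -0.974 over 46 animals (permutation p = 1e-05, the smallest that the permutations drawn can give, adjusted p = 2.67e-05 over 8 relations). Without the 2 farthest animals r was -0.978. Within single groups r ran from -0.896 to -0.995. The 95% Wilson interval of the X-linked share of 1 animal was at most 0.825 points wide and covers counting error only.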

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

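The regroupings of the animals for both medians, and the test of alleles varying against each other, were chosen only after the results were seen.

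Ttr, the transthyretin gene of the choroid plexus, stood far above the rest of its group in 4 animals. It had 46.3 CPM in P5 F1r animal 1 (others 0.742 to 3.92), 23.9 in P5 F1i animal 5 (0.774 to 4.12), 54.1 in P15 F1r animal 1 (2.03 to 10.7) and 159.3 in P15 F1i animal 4 (4.48 to 12.98). The CAST share of X-linked genes was 59.7% in P15 F1r animal 7, below the 67.5% to 70.7% of the others in its group. The same animal had the deepest library of its group, 8033000 counts against 3693000 to 5171000. Animal 7 was also the deepest of P5 F1r, with 7544000 counts against 5390000 to 6225000, and of P5 F1i, with 10320000 against 5101000 to 6521000. These were 8 of 60 groups tested for a sample apart by Dixon's criterion, which chance alone meets in about 1 of 20 groups. In P15 F1i animal 7 was the deepest too, with 7234453 counts, but did not stand apart from the next (6822504).

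Strain effects differed between ages for 2325 genes (P5 to P15), 1923 (P15 to adults) and 3675 (P5 to adults), and parental effects for 19, 16 and 30, each by a test of the difference between ages. Refitted on 3000 genes drawn at random, the strain tests called 568, 484 and 925 genes, and the highest of the other splits called 2, 1 and 1. The parental tests called 8, 3 and 9 of the same 3000, against at most 4, 0 and 1. Only the real split, 1 of 40, reached each of these 6 counts, not adjusted over the 6 tests. No smaller fraction is possible with 40 splits. The other splits mix ages whose strain effects differ, which widens their spread and can lower their counts. Chance is therefore not excluded for the parental tests, with 8, 3 and 9 genes. For the strain tests the splits argue against an absence of any difference between ages.

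The median overdispersion of the allele ratio rose by 0.0417 between P5 and P15 and by 0.0427 between P5 and adults. Each was reached by 1 of 100 regroupings, the real one, with 0.0297 and 0.0349 as the highest of the others. The regroupings mix ages whose allele ratios differ, so they cannot exclude chance between animals of 1 age. Leaving out 1 animal at a time gave a jackknife SE of 0.00728 at P5, 0.0126 at P15 and 0.00783 in adults. For the adult minus P15 difference of 0.000966, 95 of 100 regroupings were as large, up to 0.0361, and chance could not be excluded. The F1i minus F1r difference of the X-linked share did not pass between ages, at -5.69, 4.22 and -1.47 points (adjusted permutation p = 0.199, 0.268 and 0.644).

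Allele coexpression, the correlation of the 2 alleles of a gene over animals, had a median 0.398 higher at P15 and 0.320 higher in adults than at P5, and -0.0781 separated adults from P15, a step whose sign turned without thinning (0.532 at P15, 0.579 in adults). Of 100 regroupings 1, 1 and 4 were as large for the thinned medians. The highest of the others were 0.0987, 0.0705 and 0.0953. Mixed groups hold animals of 2 ages, whose differences in level move both alleles together. These regroupings therefore cannot exclude chance between animals of 1 age. Leaving out 1 animal at a time gave a jackknife SE of 0.0172 at P5, 0.0342 at P15 and 0.0612 in adults. The differences to P5 are far larger than these, while that between adults and P15 is not. A GC trend of the libraries was not the whole cause, because 0.203 of the smaller difference to P5 remained with the trend removed, nor were alleles that vary against each other at P5, where the dispersion exceeded random splits of reads by 0.0219, less than at P15 (0.0691) and in adults (0.0522). Read sampling over small differences in level between animals stays open, since random splits of each animal's reads gave a P5 median only 0.0143 above the observed one, which is consistent with it. Age itself, and litter or preparation that may have gone with age, stay open and were not tested.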

How the results depend on the processing

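The GC correction, the replicate block with GC correction and the fits without Adult F1i animal 1_1 were chosen only after the data were seen. Of 141 alternatives to the main values of the comparisons, 111 were labelled the same, 25 moved and 5 reversed. For counts of genes the label rests on the number called, and the direction of the calls was not examined. With TMM factors per allele column the strain effect at P15 counts as the same, though the CAST share of its calls went from 53.2% to 43.2%. Only the X-linked share differences could be labelled reversed. Of 2785 for single genes and for lists that camera called for age, 2759 were labelled the same, 26 lost the call and 0 reversed. For single genes the label rests on direction and call, and alternatives of the same direction without an adjusted p were left out. For these lists it rests only on the sign of the median, as camera was not rerun. Among lists that camera did not call between P5 and P15, the GC correction turned the sign of the median for oligodendrocyte precursor (-0.44 to 0.31), voltage-gated channel (-0.20 to 0.05), GABAergic and glutamatergic (0.07 to -0.23), X-linked (0.07 to -0.12) and presynaptic genes (0.03 to -0.03). The cause was not tested where no cause is given. With DESeq2 the parental effect was called for 120 genes at P5 (main value 327) and 138 in adults (344), and the cross effect for 10 at P15 (6) and 54 in adults (15). Limma on the log2 allele ratio called 177 parental effects in adults, and 36 (19) and 26 (16) changes of the parental effect from P5 to P15 and from P15 to adults. The adult cross effect had 77 genes with the replicate block, 52 with the GC correction, 174 with both, 306 when counts were summed over the first label number and 21 without Adult F1i animal 1_1. Overdispersion was called for 196, 279 and 507 genes without thinning (124, 176 and 221), where depth is higher, for 75 at P5 without the X-linked and imprinted lists, which removes genes, and for 263 at P5 and 343 in adults with no cross term. Median coexpression was 0.130, 0.532 and 0.579 without thinning (0.0923, 0.490 and 0.412), where the adult median rose above that at P15, 0.136, 0.640 and 0.532 at a mean count of 100 or more, and 0.430 at P15 and 0.290 in adults with the GC trend removed. Leaving out 1 animal at a time gave 0.0861 to 0.103, 0.475 to 0.509 and 0.355 to 0.423. The X-linked share differences between ages, none past the test, reversed with all X genes (P15 minus P5 0.422, adult minus P15 0.243, adult minus P5 0.665 points) and with the mean of per gene shares (adult minus P15 0.367, adult minus P5 0.0366). Adults that share the second label number, the block used for them, had a median correlation of their deviations of 0.205 (-0.398 to 0.738), against -0.172 for other pairs. Every alternative fixed before the data were examined was run. In simulated data of the same depth 68% of genes with a cross effect of 0.5 log2 units at P15 were called, so smaller effects between crosses can be missed.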

Other observations

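The genes of the next 2 paragraphs, and the tests of mapping that favours CAST and of an active CAST X, were chosen only after the results were seen.

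Ddc, the decarboxylase gene of serotonin and dopamine synthesis and a neighbour of the imprinted Grb10, had a parental effect at every age. Its CAST share was 45.8 ± 1.01% in F1i and 37.9 ± 1.98% in F1r at P5, 34.1 ± 0.82% and 29.9 ± 1.19% at P15, and 36.3 ± 1.04% and 33.3 ± 1.02% in adults. The effect was 0.23 ± 0.03, 0.14 ± 0.02 and 0.10 ± 0.02 log2 units, and its fall from P5 to adults passed (adjusted p = 0.037). Slc38a4, an amino acid transporter gene, had shares of 40.4 ± 2.56% and 66.4 ± 8.82% at P5 and of 21.6 ± 7.55% and 87.4 ± 13.2% in adults, so its contrast grew (-1.56 ± 0.26 log2 units, adjusted p = 2.9e-05).

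The strain balance of Tph2, Htr1a and Slc17a8 also changed between P5 and P15, as it did for 2325 of 12430 genes. The CAST share of Tph2 went from 49.9 ± 2.1% at P5 to 46.9 ± 0.89% at P15 (-0.17 ± 0.03) and 45.3 ± 0.85% in adults (-0.09 ± 0.02). The autoreceptor gene Htr1a fell from 52.4 ± 3.3% to 40.6 ± 4.6% and returned to 50.1 ± 1.5% (-0.66 ± 0.07, then 0.53 ± 0.06). The vesicular glutamate transporter gene Slc17a8 went from 40.4 ± 1.4% to 30.5 ± 2.8% and 34.9 ± 1.3%. The histocompatibility gene H2-K1 fell from 52.6 ± 8.0% at P5 to 30.3 ± 6.3% at P15, whereas adult H2-D1 was C57 biased (-3.24 ± 0.10) and adult H2-Ab1 CAST biased (4.02 ± 0.06), in 18 of 18 adults each. Total expression of the immediate early genes Egr1 (2.99 ± 0.14) and Fos (2.68 ± 0.12) rose from P5 to adults. The cholinergic gene Chat rose from 7.37 ± 1.55 to 23.4 ± 5.45 CPM over the same interval.

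Gm13340, Gm13341, Gm13339 and Gm11410 had high counts on the CAST allele in F1i and few counts in F1r, and the CAST share of genes outside the X was 0.624, 1.45 and 0.881 points higher in F1i than in F1r at P5, P15 and in adults. Of the 30-base words of these 4 genes 46.6%, 49.0%, 29.5% and 7.36% occur in mitochondrial transcripts, in the order named, and a share of words does not bound a share of reads. Over the 4 genes together the share was 33.2%, between the limits of 20% and 80% set for the test. The words were those of reference transcripts, without CAST sequence, so this test cannot decide. Reads shared with mitochondrial transcripts stay open and were not told apart from expression of the loci themselves. Both crosses carry both alleles of these genes, yet in F1r few counts came from either allele. An effect of strain alone or of parent alone on the loci themselves would leave counts on 1 allele in F1r. This argues against either alone at the loci, and does not bear on reads shared with mitochondrial transcripts. Without the 3 genes that share over 20% of their words, the difference in CAST share was 0.1997, 0.251 and -0.0382 points, so the largest remainder of 0.251 also lay between its limits. Parental origin stays open together with strain for these 4 genes and by itself for the remainder, and neither was tested.

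The CAST X gave more counts than the C57 X in every animal. Mapping that favours CAST reads was argued against, since the highest CAST share of Xist in any animal was 43.9%, and genes outside the X stood at 49.9% to 51.5%. A CAST X that is more often the active one may account for it, as the shares of Xist and of other X-linked genes ran opposite over the 46 animals (r = -0.978, group means removed). The lowest share in any animal of either cross was 57.4%, so parental origin is not the whole cause and stays open only for the difference between crosses. The excess common to both crosses went with the CAST strain, but how strain acts stays open. No test separated choice of the X from later selection of cells.

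Lower myelin genes in F1i at P5 may reflect an earlier stage of development of the F1i animals. Over the genes outside the myelin list the F1i minus F1r difference at P5 ran against the change from P5 to P15 (Spearman rho = -0.259 across genes, which are not independent replicates), as that hypothesis requires. A value as large came from 30 of 1716 splits of the P5 animals. Parents, litter and time of sampling stay open and were not tested.

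Chance was excluded for the age tests, as 1 of 100 splits, the real one, reached their counts. These were 11377, 10183 and 11201 genes for P15 over P5, adults over P15 and adults over P5, and the other splits called at most 3150, 5367 and 3043. It was likewise excluded, with 1 of 100 each, for parental effects at P5, P15 and in adults (327, 89 and 344 genes, against at most 50, 69 and 1). For strain effects 7052, 7010 and 8597 genes stood against at most 3930, 8 and 5354, again with 1 of 100 each. The cross effect at P5 was reached by 1 of 100 splits (151 genes, at most 58 in the others). For the 6 genes at P15 the number was 3 of 100 and for the 15 in adults 2 of 100, not adjusted over the tests. The highest of the other splits called 1024 genes at P15 and 274 in adults, which points to a structure of the samples that the crosses do not follow. Chance is therefore not excluded for the cross effect at P15 or in adults.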
